A study of Mus musculus with 24 samples.

How the data were processed

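Total RNA from mouse brain was sequenced in 24 libraries, 6 per group, and the labels' protocols describe 6 mice per group, so replicates are animals. Per the labels' protocols, RNA was purified with a lipid tissue kit, checked for integrity and sequenced on an Illumina HiSeq instrument. The files deposited by the authors hold whole-number counts per gene, not normalized, with the summary lines that HTSeq's counter writes. HISAT2 (version not given in the sources used here), HTSeq 0.6.0, DESeq2 1.6.3 and the mm10 build are named per the submitters' processing notes, which give no order or role for them. The strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. Gene symbols and coordinates come from the GENCODE M21 annotation of GRCm38 (the mm10 assembly), which need not be the release the authors counted with. It gave a symbol for 52489 of the 52636 identifiers (99.7%), and 15491 identifiers were at 0 in all libraries. Where identifiers shared a symbol (83 cases), the most abundant kept it.

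Each deposited count file ends in 5 summary lines that name no gene, and these were left out of library sizes and tests. Reads outside genes took 7.52 to 11.1% of the file total in the syn libraries and 4.47 to 6.37% in the gfap libraries. Ambiguous reads took 3.19 to 7.46% and reads with more than 1 alignment 13.7 to 15.6%. Counts in genes summed to between 41596313 and 69652824 per library. CPM values computed from the deposited counts use TMM-scaled library sizes. All 60 pairs of libraries within a group differed by more than sampling noise (chi-square per gene 8.17 to 191.58, where 1 marks counting noise alone), so no library was counted as a copy of another.

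Groups were taken from the cell type and genotype labels, and replicate numbers follow accession order and name a library only. Genes were filtered with filterByExpr, which left 19726. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 1 model of 4 groups over all 24 libraries, 20 residual degrees of freedom and robust quasi-likelihood estimation. The common dispersion was 0.0198. The contrasts were Cre-positive minus Cre-negative in each line, the difference of these contrasts, and the Cre-negative groups of the syn line minus the gfap line. Benjamini-Hochberg adjusted p values under 0.05 were called, and edgeR's p values come from its quasi-likelihood F test. Intervals are 95% and cover the spread between animals within groups.

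The 44 fixed lists cover pathways, cell types and brain regions, 766 genes in all. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 44 lists within a contrast. Camera with a correlation estimated per list and fry, a rotation test of each list against no change, were the alternatives. Values from fry are those of its test for a shift in 1 direction unless the test of either direction is named. Counts of members that passed are given over all genes tested and adjusted over the list alone. The lists, the groups, the tests, the named-gene rule and most alternatives were fixed before the data were examined.

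The rule for named genes took Slc1a2, and for each Cre comparison the called genes with the smallest p and the largest change. With fewer than 10 called, all were named and the genes with the smallest unadjusted p filled up to 10 as values. From each list that passed camera or held a called gene, up to 4 members with the smallest p were taken, and up to 3 from 8 lists of special interest. For the difference between lines and for the Cre-negative groups, 5 genes per direction were taken. Predicted genes with provisional names were counted and not named. Outside this rule Ttr and the list members named for the Cre-negative groups were chosen after their values were seen. Some genes that the rule takes are not reported here.

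The fit was tested on simulated data drawn from the real genes' means and library sizes over 19726 genes, with 50 genes changed at each of 4 fold sizes. For the neuronal comparison it called 22% at 1.25-fold, 62% at 1.5-fold, 76% at 2-fold and 86% at 3-fold, with 8 false calls, 6.11% of all calls. For the astrocytic comparison it called 38%, 64%, 62% and 90% at these sizes, with 6 false calls, 4.51% of all calls. All recovered changes had the right sign. A list shifted on purpose passed camera with the preset correlation (adjusted p = 4.6e-24) and with an estimated one (1.4e-08). Simulated genes varied independently of each other, so this says nothing about how often the preset correlation passes lists by chance. Simulated libraries also held no structure shared across genes, so the shares of recovered and false calls need not hold for the real libraries.

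Alternatives covered scaling (RLE and upper-quartile factors), filtering (none, or at least 1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom with quality weights, each line fitted alone, no robust estimation, and the first number of the sample title as a random block. They also covered 1 surrogate variable (sva 3.50.0), Xist as a covariate, and each library of the compared groups left out in turn. Xist held 0 to 15 counts per library and the Y-linked gene Kdm5d 1173 to 4289, so by these genes all 24 libraries read as male. The Xist covariate thus had no difference of sex to adjust for. Chosen after the data were seen were leaving out 2 doubted libraries, a choroid plexus score as covariate, and offsets for GC content and length, which were known for 99.8% of tested genes. The doubted libraries were syn-Cre-negative 5, rich in ribosomal RNA, and gfap-Cre-negative 4, apart on the third principal component. For other groupings of the samples, 100 regroupings including the real one were refitted. Figures were drawn with matplotlib 3.10.9 from tables handled with pandas 2.3.3 in Python 3.11.15.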

Results

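RNA was sequenced from brain tissue of 24 mice in 4 groups of 6, from a pair of Cre lines. The study asks how loss of the glutamate transporter EAAT2, encoded by Slc1a2, acts when it is aimed at neurons or at astrocytes. EAAT2 takes up glutamate released at synapses and sits mostly on astrocytes, with a smaller share on neuronal terminals. Cre recombinase removes a stretch of DNA placed between its target sites. The syn-Cre line is the neuronal arm and the gfap-Cre line the astrocytic arm, each with a Cre-positive and a Cre-negative group. The labels give the Cre-positive genotype as EAAT2 −/− in the syn line and EAAT2 Δ/+ in the gfap line. Gene-level totals ran from 41596313 to 69652824 counts per library, and 19726 genes were tested.

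Slc1a2 (ENSMUSG00000005089, GRCm38/mm10 chromosome 2, 102658659 to 102790784) did not pass the test of a difference in either line. In the libraries labelled syn-Cre-positive it stood at 3009, 3029, 3235, 3033, 3148 and 2616 CPM (counts scaled to a common library size) in replicates 1 to 6. The libraries labelled syn-Cre-negative held 3422, 3461.5, 3265, 3318, 3239.5 and 3227 CPM. The libraries labelled gfap-Cre-positive held 3854.5, 3636, 3249, 3043, 3519 and 3579.8 CPM, and those labelled gfap-Cre-negative 3929.7, 3980.2, 3595, 2494, 3677 and 3430.3 CPM. Group means were 3012 ± 213 and 3322 ± 98.7 CPM in the syn line and 3480.3 ± 290.1 and 3518 ± 542 CPM in the gfap line (SD, n = 6 each, Cre-positive first). The log2 fold change was −0.14 in the syn line (SE 0.08, 95% interval −0.30 to 0.02, edgeR adjusted p = 1.00) and −0.02 in the gfap line (SE 0.08, −0.17 to 0.14, adjusted p = 1.00). In the syn line 5 of 6 Cre-positive libraries lay below the lowest Cre-negative one, and the interval of the difference includes 0. In the gfap line the value depends on library gfap-Cre-negative 4, the lowest of its group, and was −0.10 without it, which did not pass either. The count sums the whole gene, so a deleted exon need not lower it, and which exon is deleted is not given in the sources used here. Every direction below is therefore one between libraries labelled Cre-positive and libraries labelled Cre-negative.

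**Figure D1:**
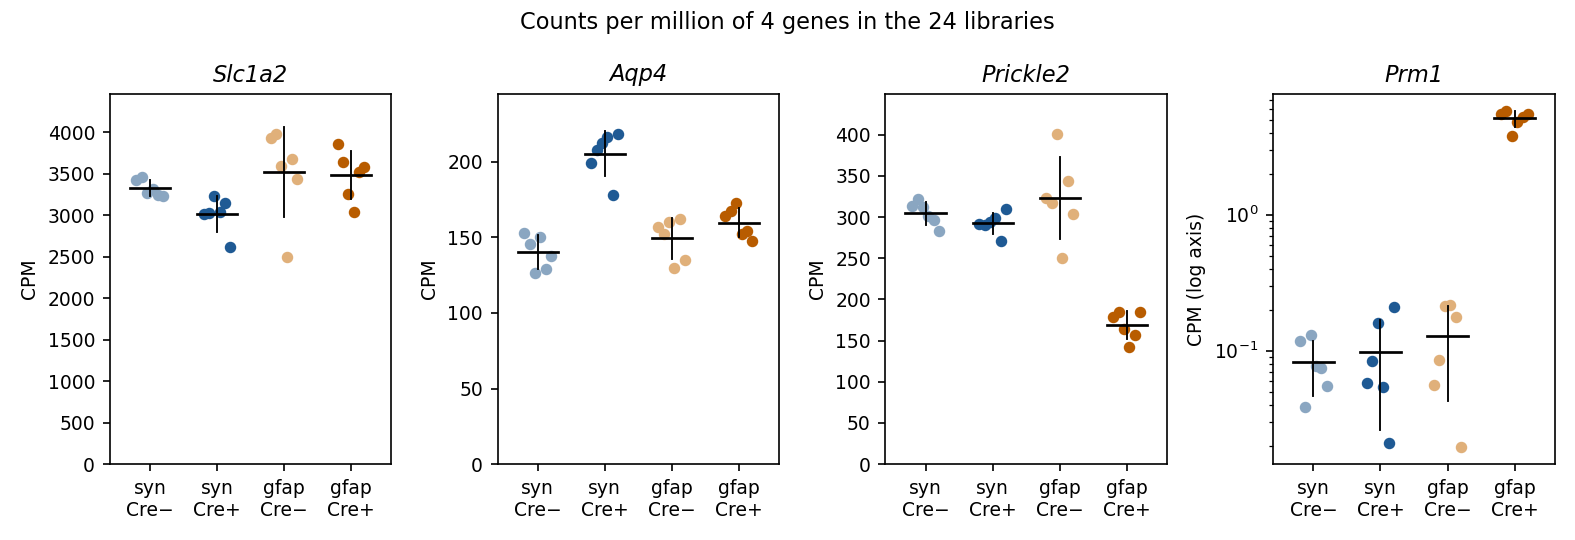
CPM of Slc1a2, Aqp4, Prickle2 and Prm1 (y axes, Prm1 on a log axis) in the 4 groups of 6 libraries (x axis); points are libraries, horizontal lines group means and vertical lines 1 SD. Aqp4 is higher in the syn line's Cre-positive libraries, Prickle2 is lower and Prm1 higher in the gfap line's Cre-positive libraries, and Slc1a2 overlaps within both lines.

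The neuronal arm compares libraries labelled syn-Cre-positive with those labelled syn-Cre-negative. Aqp4, the water channel of astrocyte endfeet (ENSMUSG00000024411, chromosome 18, 15389496 to 15410982), rose from 140.3 ± 11.1 to 205 ± 15.0 CPM (SD, n = 6 each), a 1.46-fold difference with no overlap between the groups. Its log2 fold change was 0.55 (SE 0.06, 95% interval 0.42 to 0.68, edgeR adjusted p = 2.0e-05). Among 18 astrocyte marker genes measured, 3 were higher when adjusted over the list alone, Aqp4, the gap junction gene Gja1 (log2 fold change 0.17) and the filament gene Gfap (0.22), while the gap junction gene Gjb6 was lower (−0.32, and −0.21 without library syn-Cre-negative 2). Over all genes tested, Aqp4 was the 1 member that passed. As a set the astrocyte list did not shift in 1 direction (camera adjusted p = 0.0733; adjusted p = 0.594 with an estimated correlation).

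Aqp4 was the 1 gene called higher by edgeR in the neuronal arm, and 0 were called lower, with 922 genes at an unadjusted p under 0.05 where chance alone gives 986.3. DESeq2 called 15 genes, 8 higher and 7 lower, and limma-voom with quality weights called 8, 4 in each direction. The genes next in order of p did not pass in edgeR and are given as values. Mmp14, a membrane-bound matrix metalloproteinase, had a log2 fold change of 0.56, the endothelin receptor gene Ednrb 0.34 and the homeodomain gene Hopx 0.44, each at adjusted p = 0.0697. Hif3a, a hypoxia-inducible factor subunit, stood at 3.42 ± 1.13 against 8.61 ± 2.54 CPM (SD, n = 6 each; log2 fold change −1.33, edgeR adjusted p = 0.168). Myrip (−0.25, adjusted p = 0.132), Pthlh (−0.96, 0.168) and Nxph1 (−0.46, 0.263) were lower by value, and Rftn1 (0.33) and Tst (0.37) higher by value, both at 0.308.

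Of 44 gene lists, 10 passed camera in the neuronal arm, 5 up and 5 down, and 3 of them also passed with an estimated correlation. Glucocorticoid-induced genes, which respond to corticosterone, were lower than other genes as a list: all 15 had negative log2 fold changes, with a median of −0.20 (camera adjusted p = 1.2e-12; adjusted p = 0.0486 with an estimated correlation). Of these, 8 were lower adjusted over the list alone and 0 over all genes tested, among them the lipid droplet gene Plin4 (−1.46), Map3k6 (−0.62), Sult1a1 (−0.50) and Tsc22d3, a classical glucocorticoid target (−0.49). Cholesterol synthesis genes were also lower as a list, 18 of 20 being negative with a median of −0.11 (camera adjusted p = 1.4e-09; adjusted p = 0.0486 with an estimated correlation). In that list 5 genes were lower adjusted over the list alone and 0 over all genes tested, among them Fdft1 (−0.23), Hmgcs1 (−0.21) and Sqle (−0.18). Circadian clock genes were lower as a list too, with 17 of 18 negative and a median of −0.14 (camera adjusted p = 1.1e-06; adjusted p = 0.0486 with an estimated correlation). No clock gene passed alone, 0 over all genes and 0 adjusted over the list alone, and the values were −0.28 for Per2, −0.17 for Nr1d2, −0.17 for Npas2 and −0.18 for Per1. Without library syn-Cre-negative 2 Per2 was at −0.16. By fry's test of a shift in 1 direction against no change, the 3 lists had adjusted p values of 0.0597 to 0.0772 and did not pass. Its test of changes in either direction passed for the cholesterol list (adjusted p = 0.000586) and the astrocyte list (1.1e-06), and for no other list in this arm. When any 1 of the 12 syn libraries was left out, the glucocorticoid list (adjusted p = 0.0599 to 0.153) and the cholesterol list (0.0597 to 0.123) no longer passed with an estimated correlation, and the clock list passed in 2 of 12 cases.

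**Figure D2:**
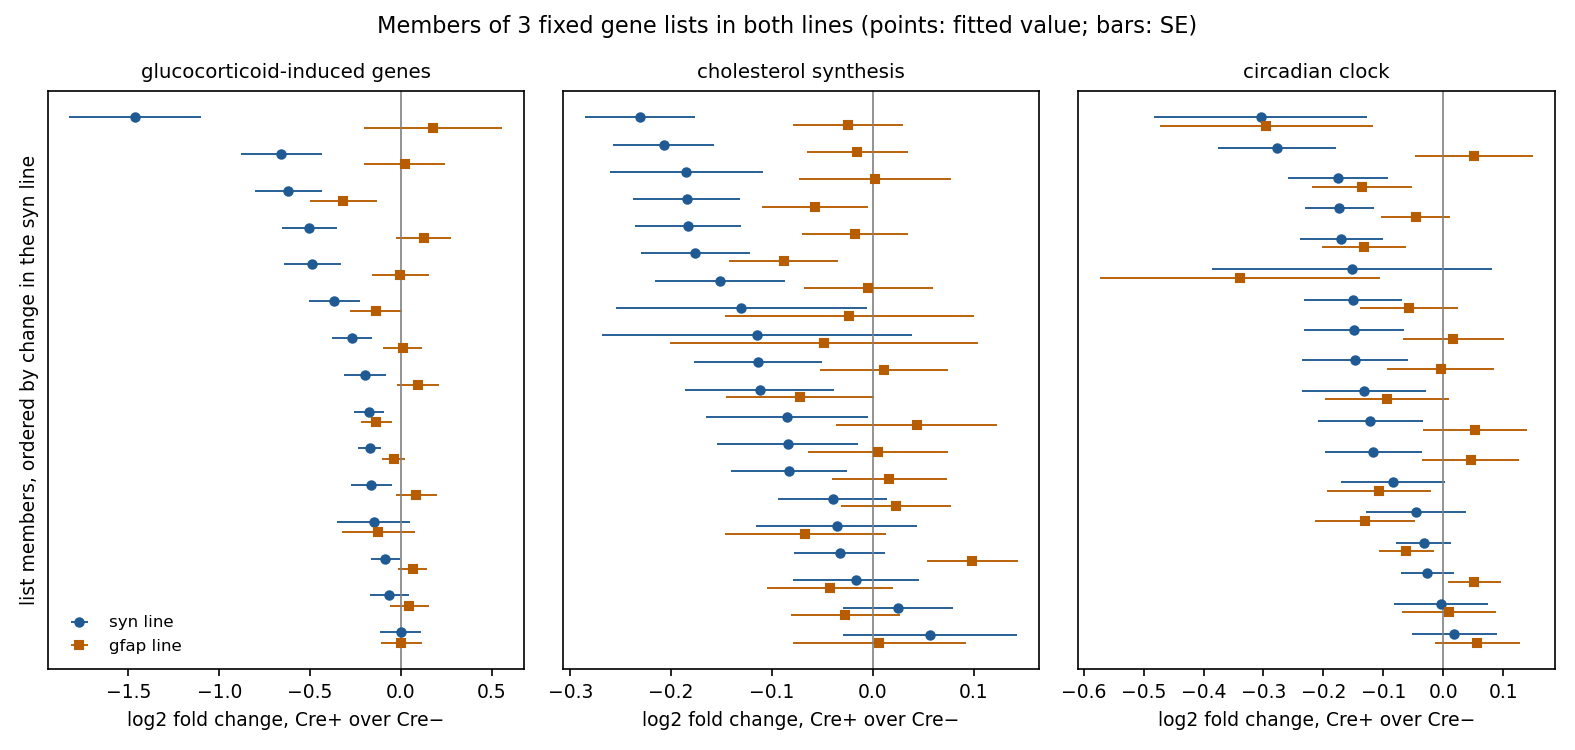
Log2 fold changes, Cre-positive over Cre-negative (x axes), of each member (y axes, ordered by the change in the syn line) of the glucocorticoid-induced, cholesterol synthesis and circadian clock lists in the syn line (circles) and the gfap line (squares), with bars of 1 SE. In the syn line 15 of 15, 18 of 20 and 17 of 18 members lie below 0.

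A further 7 lists passed camera in the neuronal arm with its preset correlation and lost that call with an estimated one. Heat shock and unfolded protein genes were lower by value in 19 of 20 members, such as Xbp1 (−0.28) and the chaperone Hspa5 (−0.33), at adjusted p = 8.4e-05, and adjusted p = 0.594 with an estimated correlation. Immediate early genes, which mark recent neuronal activity, were negative in 17 of 20, with Egr1 at −0.45 and Fosb at −0.43 (0.0154; adjusted p = 0.819 with an estimated correlation). Without library syn-Cre-negative 2 the values were −0.091 for Egr1, −0.14 for Fosb and −0.17 for Xbp1, and limma-voom gave −0.19 for Hspa5. Mature oligodendrocyte genes were positive in 11 of 16, with Opalin at 0.26 (0.0112; adjusted p = 0.819 with an estimated correlation). Meningeal fibroblast genes were positive in 13 of 15, with Col1a1 at 0.56, or 0.31 without library syn-Cre-positive 6 (0.0112; adjusted p = 0.819 with an estimated correlation). Hippocampal genes were positive in 12 of 15 (0.0154; adjusted p = 0.594 with an estimated correlation) and cerebellar genes in 11 of 13 (0.0154; adjusted p = 0.0587 with an estimated correlation). In each of those 6 lists, 0 members passed over all genes tested and 0 adjusted over the list alone. Tryptophan and kynurenine genes were positive in 10 of 17 (0.0413; adjusted p = 0.475 with an estimated correlation), with 0 called over all genes and 3 higher adjusted over the list alone: Tph1 (1.89), Afmid (0.71) and Tdo2 (0.36). Tph1 and Afmid lie below 1 CPM on average. Library syn-Cre-positive 5 held 2.47 CPM of Tph1 against 0.187 to 0.399 CPM in the other 5 of its group, and without it the Tph1 log2 fold change was 0.76.

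Lists for glutamate uptake and recycling (camera adjusted p = 0.599), disease-associated microglia (0.599), class I antigen presentation (0.983), pan-reactive astrocytes (0.633) and orthologues of Alzheimer disease risk genes (0.633) did not pass in the neuronal arm. Homeostatic microglia genes were positive in 15 of 19 and did not pass either (0.0840). Choroid plexus genes, a marker of how much ventricle lining was dissected, were negative in 16 of 16 with a median of −0.47 and did not pass (0.359). The choroid plexus gene Ttr exceeded 1000 CPM in 3 of 6 libraries of each syn group and in 0 of 12 gfap libraries. Library syn-Cre-negative 2 had the highest mean of the glucocorticoid list, 4.99 log2 CPM against 4.31 to 4.49 in the other 5 of its group.

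The astrocytic arm compares libraries labelled gfap-Cre-positive with those labelled gfap-Cre-negative. Prm1, which encodes a protamine that packs sperm DNA (ENSMUSG00000022501, chromosome 16, 10796326 to 10805839), rose from 0.128 ± 0.0852 to 5.09 ± 0.703 CPM (SD, n = 6 each). That is 201 to 293 counts per library against 1 to 14, a log2 fold change of 5.28 (SE 0.32, 38.8-fold, edgeR adjusted p = 5.3e-12). Prickle2, a planar cell polarity gene expressed in neurons (ENSMUSG00000030020, chromosome 6, 92370908 to 92706155), fell from 323 ± 49.7 to 169 ± 17.2 CPM (SD, n = 6 each). Its log2 fold change was −0.94 (SE 0.08, 95% interval −1.09 to −0.78, edgeR adjusted p = 7.8e-09), a change of −47.8%, and the groups did not overlap. These 2 genes, 1 higher and 1 lower, were all that edgeR called, with 590 genes at an unadjusted p under 0.05 where chance alone gives 986.3. DESeq2 and limma-voom called the same 2.

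The next genes in order of p in the astrocytic arm all had an adjusted p of 1.00 and are values only. Hist3h2a was at 0.29, Cdk3-ps at 0.68 and the protease gene Htra4 at 0.50, while the death receptor gene Fas was at −0.78, Pigz at −0.40, Amn at −0.84, Tmem125 at −0.43 and Pde1c at −0.28. Without library gfap-Cre-negative 4 Amn was at −0.47. Aqp4 was at 0.10 in this arm (SE 0.06, adjusted p = 1.00) and at 0.058 without that library.

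In the astrocytic arm 12 lists passed camera with its preset correlation, 10 up and 2 down, and 0 passed with an estimated correlation, where adjusted p ran from 0.617 to 0.837. By fry's test of 1 direction 0 passed, and the smallest adjusted p was 0.792. Homeostatic microglia genes were positive in 19 of 19, with Olfml3 at 0.25 and Selplg at 0.15 (1.2e-05; adjusted p = 0.617 with an estimated correlation). Mitochondrially encoded genes were positive in 12 of 13, with mt-Nd2 at 0.15 and mt-Cytb at 0.14 (2.0e-06; adjusted p = 0.617 with an estimated correlation). Meningeal fibroblast genes were positive in 15 of 15, with the collagen gene Col3a1 at 1.13, or 0.75 by limma-voom (1.2e-05; adjusted p = 0.617 with an estimated correlation). Interferon-stimulated genes were positive in 21 of 25, with Stat2 at 0.17 (0.00294; adjusted p = 0.617 with an estimated correlation), and pan-reactive astrocyte genes in 12 of 13, with Cxcl10 at 1.06 (0.00564; adjusted p = 0.617 with an estimated correlation). Astrocyte genes were positive in 16 of 18 (0.0308; adjusted p = 0.617 with an estimated correlation), endothelial genes in 14 of 15 (0.0165; adjusted p = 0.617 with an estimated correlation) and hippocampal genes in 13 of 15 (0.0165; adjusted p = 0.617 with an estimated correlation). Disease-associated microglia genes were positive in 15 of 21 (0.0165; adjusted p = 0.674 with an estimated correlation) and heat shock genes in 17 of 20 (0.0196; adjusted p = 0.837 with an estimated correlation). Mature oligodendrocyte genes were negative in 16 of 16, with Opalin at −0.19 and Mag at −0.15, or −0.096 for Mag without library gfap-Cre-negative 4 (0.00294; adjusted p = 0.807 with an estimated correlation). Presynaptic vesicle genes were negative in 19 of 21, with Sv2a at −0.10 (0.00323; adjusted p = 0.617 with an estimated correlation). In each of these 12 lists, 0 members passed over all genes tested and 0 adjusted over the list alone. The glucocorticoid (0.891), cholesterol (0.655), clock (0.113), glutamate uptake (0.686), kynurenine (0.853) and Alzheimer risk (0.328) lists did not pass.

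The difference between the arms, neuronal minus astrocytic, was tested directly. The labels give EAAT2 −/− for the Cre-positive syn mice and EAAT2 Δ/+ for the Cre-positive gfap mice. The labelled genotype, the line and the targeted cell type thus change together and cannot be told apart in this contrast. The same limit holds for every later comparison of the arms. Prm1 (−5.04, SE 0.61) and Prickle2 (0.88, SE 0.11) differed between the arms, both at edgeR adjusted p = 5.7e-05, and no other gene did, with 691 at an unadjusted p under 0.05. For Aqp4 the difference was 0.45 (SE 0.09) and did not pass over all genes (edgeR adjusted p = 0.109), whereas adjusted over the astrocyte list alone it passed (0.000300). DESeq2 and limma-voom each called 3 genes, adding Aqp4 (adjusted p = 0.00710 and 0.0118), which edgeR also called without library syn-Cre-positive 5 (0.0195) or gfap-Cre-negative 4 (0.0110). The glucocorticoid list was negative in 15 of 15 for the difference, with Plin4 and Sult1a1 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 1.7e-06; adjusted p = 0.536 with an estimated correlation). The cholesterol list was negative in 16 of 20 (0.000155; adjusted p = 0.536 with an estimated correlation). In all 7 lists passed camera for the difference and 0 passed with an estimated correlation, so a difference between the arms in these lists rests on the preset correlation.

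Across the 19726 genes, the log2 fold changes of both arms had a Pearson correlation of 0.07 and a Spearman correlation of 0.03, with the same sign in 50.6%. Genes are not independent replicates, and the jackknife SE over libraries of this Pearson correlation was 0.0884. Among the 10531 genes with a mean log2 CPM of at least 3, the Pearson correlation was 0.16 and the Spearman correlation 0.04. No gene was called in both arms, where 5.1e-05 genes higher in both were expected by chance. The lack of shared calls therefore carries no weight on whether the arms agree.

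Genes near the targeted locus were examined because a floxed allele can carry linked DNA of another strain. Of 90 tested genes within 10 Mb of Slc1a2, 0 were called by edgeR in either arm. With 1 gene called in all in the neuronal arm and 2 in the astrocytic arm, this 0 carries no weight on linked DNA. Between the Cre-negative groups 31 of the 90 differed, against 31.2% elsewhere (Fisher's exact test, two-sided, odds ratio 1.16, p = 0.496). Within 5 Mb 15 of 48 differed (Fisher's exact test, odds ratio 1.00, p = 1.00). Within 20 Mb 109 of 284 differed, or 38.4% against 31.1% elsewhere (Fisher's exact test, two-sided, odds ratio 1.38, 95% interval 1.07 to 1.76, unadjusted p = 0.00986), so the test was passed at the widest distance and not at the other distances.

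The Cre-negative groups of both lines differed in 6161 genes, 2884 higher and 3277 lower in the syn line, which is 31.2% of those tested. The share higher was 46.8%, against 52.8% with RLE factors and 58.5% with upper-quartile factors, so which direction held more genes depends on the scaling. Muc3a, a mucin gene (log2 fold change 1.86), Shkbp1 (1.08), Mbd6 (1.07), the focal adhesion gene Pxn (0.76) and Nrbp2 (0.67) were higher in the syn line. Eif3j1 (−0.75) and Haus2 (−0.75), a translation initiation subunit and a spindle protein gene, were lower, as were the leucine catabolism gene Ivd (−0.44), Hnrnpa3 (−0.40) and Snn (−0.40). All 10 had edgeR adjusted p values from 1.1e-08 to 2.8e-07. Choroid plexus content varied within the syn line, and with its score as a covariate, an alternative chosen after the data were seen, 5096 genes differed, 4614 of them among the 6161. Line, strain background and any batch follow the same groups here and cannot be told apart, so Cre effects were compared within a line.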

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

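The tests of the protamine locus, of an inserted transgene, of the Y-linked genes and of the choroid plexus score were chosen only after the data they bear on were seen, and the other tests of the first 2 patterns were written after the pattern was noticed but before their own outcome was known.

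Prm1 and Prickle2 stood apart from all other genes in the gfap line, and their effects differed between the lines by −5.04 and 0.88 on the log2 scale. A rise of the whole protamine locus is argued against by the counts of its other genes. Prm2, Prm3 and Tnp2 together had 7 counts against 10, a ratio of 0.769 with 3 added on each side. The ratio of the summed Prm1 counts, with 3 added likewise, was 33.8. A stretch of linked strain background is argued against too, since 2.86% of the other tested genes within 2 Mb of Prickle2, 1 of 35, reached an unadjusted p under 0.05, with a median log2 fold change of 0.01. A hypothesis that remains is that the gfap-Cre transgene, which may carry a Prm1 fragment as some Cre constructs do, sits in 1 allele of Prickle2: the log2 fold change of −0.94 has an interval (−1.09 to −0.78) that holds the −1 of a lost allele, and the lowest Prm1 value in the 6 libraries, 3.81 CPM, exceeds the highest of the other 18, 0.217 CPM; these values prompted the hypothesis and do not test it independently, and reads across an insertion were not analysed here. An effect of the Slc1a2 deletion itself stays open as untested, because every library with Cre also carries the label of the deletion.

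The glucocorticoid, cholesterol and clock lists were lower in the libraries labelled syn-Cre-positive, with 49 of 52 members below 0 and a median log2 fold change of −0.15, against −0.00 in the gfap line. That pooled gfap value covers a clock list that leaned lower there too, at a mean of 5.65 against 5.71 log2 CPM (Cre-positive first). The means were 5.42 against 5.43 for cholesterol and 4.17 against 4.19 for glucocorticoid genes. For the difference between the lines the clock list did not pass camera, and 0 lists passed with an estimated correlation. A single deviating library is argued against for the pooled members of these lists. Leaving out 1 syn library kept at least 78.1% of their median, which met the limit set beforehand. By list, at least 82.8% was kept for glucocorticoid, 70.0% for cholesterol and 64.5% for clock genes. The cholesterol and clock values fall short of that limit, so the pooled value does not settle this for each of those lists alone. For a shift of clock phase alone, the first component of the clock list, holding 42.3% of that list's variance, was added as a covariate. The cholesterol median was then −0.075 (SE 0.026, −0.11 without), which met the limit set beforehand for arguing against such a shift. The means of 3 morning and 8 evening clock genes did not have opposite signs (−0.052, SE 0.060, and −0.16, SE 0.034). These SEs are over list members measured in the same animals, not over animals, and the covariate is partial. The test therefore does not decide on clock phase. Choroid plexus tissue is argued against, as 96.5% of the median remained with its score as a covariate. A clock shift, alone or as a part, stays open, and handling stress or the deletion itself may account for the pattern, which no label or group here separates.

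In library syn-Cre-positive 3 the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y stood at 76.2, 34.9, 142 and 145 CPM, each far above the other 5 of its group. Their log2 deviations were 1.08, 0.96, 1.02 and 1.13, the lowest being 0.96. Scaling or depth is argued against, because no chromosome's genes other than Y deviated by a median of more than 0.0245. A second copy of the Y chromosome in this animal may account for them, a hypothesis that the same 4 values prompted and so do not test independently, and no biological explanation from the study's groups was tested.

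Of 122 sets of 6 values examined for a library far from the others, 20 stood out where chance gives about 1 in 20, or 6.1. Besides the Y-linked values above, Uty was at 21.7 CPM in syn-Cre-negative 3. Slc1a2 was low in syn-Cre-positive 6 (2616 CPM) and in gfap-Cre-negative 4 (2494 CPM). Among other genes, Ednrb was low in syn-Cre-positive 1 (50.2 CPM), Hopx low (38.2 CPM) and Nxph1 high (38.9 CPM) in syn-Cre-positive 5, and Pthlh high in syn-Cre-negative 5 (2.28 CPM). Cdk3-ps was high in gfap-Cre-negative 1 (1.08 CPM) and Amn in gfap-Cre-negative 4 (8.08 CPM). Ribosomal RNA took 3.95% of counts in syn-Cre-negative 5 and 1.19% in gfap-Cre-negative 4, and reads outside genes took 11.1% in syn-Cre-negative 5. Mean log2 CPM was high for glucocorticoid genes (4.99) and oligodendrocyte genes (7.28) in syn-Cre-negative 2, low for cerebellar genes in syn-Cre-negative 3 (2.57), and high for meningeal genes in gfap-Cre-negative 5 (3.34).

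The lists whose effect differed between the lines by the preset camera test had these mean log2 differences, neuronal minus astrocytic: −0.35 for immediate early, −0.10 for mitochondrially encoded, −0.090 for cholesterol, −0.24 for heat shock, −0.35 for glucocorticoid, 0.18 for oligodendrocyte and 0.30 for cerebellar genes. None of the 7 passed with an estimated correlation, where adjusted p ran from 0.439 to 0.954.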

How the results depend on the processing

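The alternatives without 2 doubted libraries, with a choroid plexus score and with GC and length offsets were chosen only after the data were seen. No paired analysis was possible because replicate numbers only follow accession order. The first numbers of the sample titles repeat within groups and are never shared between groups. What they mark is not given in the sources used here; if they are cages or litters, animals that share one are not independent, these numbers lie within the groups compared, and p values would be too small. The cause was not tested for any change below.

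The astrocytic count was 2 genes under all 26 alternatives, and Aqp4 was called in the neuronal arm in all 26. The neuronal count of 1 became 5 with no filter, 15 with DESeq2, 8 with limma-voom, 2 with the syn line alone, 2 with 1 surrogate variable, 2 without the doubted libraries and 5 with GC and length offsets. Leaving out 1 library gave 1 to 3 genes: 2 without syn-Cre-positive 1, syn-Cre-negative 3 or syn-Cre-negative 5, and 3 without syn-Cre-positive 5. The difference between arms went from 2 to 4 genes without the doubted libraries, Aqp4 among them (adjusted p = 0.0242). It was 3, with Aqp4 added, under DESeq2, limma-voom, no filter (0.0204) and GC and length offsets (0.0192), and without syn-Cre-positive 5 (0.0195) or gfap-Cre-negative 4 (0.0110). Between the Cre-negative groups the count ran from 4387 to 6595, and the share higher was 52.8% with RLE factors and 58.5% with upper-quartile factors against 46.8%. Scalings moved the median of all genes by at most 0.04 log2. Slc1a2 in the gfap line changed sign, never passing: 0.032 with 1 surrogate variable, 0.012 with offsets, and −0.10 to 0.023 when 1 library was left out (positive without gfap-Cre-positive 3 or 4 or gfap-Cre-negative 1 or 2, lowest without gfap-Cre-negative 4). In the syn line it stayed between −0.16 and −0.10. Leaving aside Slc1a2 within each line, of 3854 alternatives for the 148 other results of named genes 3822 kept direction and side of the threshold, 32 passed where the main value had not, and 0 reversed. Most of these 148 results did not pass in the main fit, so keeping the side mostly means still not passing. Many genes were taken for a small p in these same libraries, which makes a reversal unlikely. Sizes could still move: in the neuronal arm Egr1 ran from −0.56 to −0.09 and Tph1 from 0.76 to 2.20. Libraries sharing a title number had a consensus correlation of 0.0343.

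Of 606 alternatives for the 29 list results, 461 kept the call and 145 lost it. With an estimated correlation the adjusted p values of lost neuronal lists were 0.0587 (cerebellum), 0.475 (kynurenine), 0.594 (heat shock, hippocampus) and 0.819 (immediate early, oligodendrocyte, meningeal). Astrocytic ones were 0.674 (disease-associated microglia), 0.807 (oligodendrocyte), 0.837 (heat shock) and 0.617 (the other 9). Those of the difference were 0.439 (cerebellum), 0.536 (cholesterol, glucocorticoid), 0.847 (heat shock), 0.900 (oligodendrocyte) and 0.954 (immediate early, mitochondrial). With fry, neuronal values were 0.0597 (cholesterol, clock, cerebellum), 0.0772 (glucocorticoid), 0.574 (kynurenine), 0.697 (heat shock, hippocampus) and 0.873 (immediate early, oligodendrocyte, meningeal). Astrocytic ones were 0.856 (disease-associated microglia), 0.898 (heat shock, oligodendrocyte) and 0.792 (the other 9), and those of the difference 0.434 (cerebellum), 0.743 (cholesterol, glucocorticoid) and 0.994 (the other 4).

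With 1 surrogate variable 6 lists lost their call: astrocytic astrocyte (0.0987), disease-associated microglia (0.155), endothelial (0.0896), presynaptic (0.0896) and heat shock genes (0.0545), and cerebellar genes in the difference (0.0505). Cerebellar genes in the difference also lost it with RLE factors (0.0608) and the choroid score (0.0558). Without the doubted libraries astrocytic astrocyte and hippocampal (0.0695 each), endothelial (0.0844) and oligodendrocyte genes (0.138), neuronal oligodendrocyte (0.0633) and meningeal genes (0.125), and cerebellar genes in the difference (0.135) lost it.

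Adjusted p ranges when 1 library was left out were, in the neuronal arm, 0.00616 to 0.107 for cerebellar, 1.2e-09 to 0.0888 for heat shock, 0.000183 to 0.148 for hippocampal, 2.8e-05 to 0.996 for immediate early, 1.7e-09 to 0.389 for oligodendrocyte, 4.6e-06 to 0.517 for meningeal and 0.00448 to 0.260 for kynurenine genes. In the astrocytic arm they were 0.00504 to 0.270 for astrocyte, 0.00124 to 0.228 for disease-associated microglia, 0.000405 to 0.280 for endothelial, 0.00564 to 0.228 for heat shock, 0.000254 to 0.178 for hippocampal, 8.5e-08 to 0.214 for oligodendrocyte and 4.9e-05 to 0.0953 for presynaptic genes. For the difference they were 0.0163 to 0.159 for cerebellar, 9.2e-06 to 0.281 for immediate early and 7.8e-05 to 0.195 for mitochondrial genes. In the neuronal arm a call was lost when any 1 of these was left out: syn-Cre-positive 3 or 5 for cerebellar genes, syn-Cre-negative 1 or 2 for heat shock genes, and syn-Cre-positive 3 or 5 or syn-Cre-negative 2 for immediate early genes. The same held for syn-Cre-positive 1, 2 or 6 or syn-Cre-negative 4 or 6 (hippocampal), syn-Cre-positive 5 or syn-Cre-negative 1, 3 or 4 (oligodendrocyte), syn-Cre-positive 5 or 6 or syn-Cre-negative 1, 2, 5 or 6 (meningeal), and syn-Cre-positive 2, 5 or 6 or syn-Cre-negative 1, 2 or 6 (kynurenine). In the astrocytic arm these were gfap-Cre-positive 3, 4 or 5 or gfap-Cre-negative 3, 4 or 6 (astrocyte), gfap-Cre-positive 3 or 4 or gfap-Cre-negative 1 or 2 (disease-associated microglia), and gfap-Cre-positive 4 or 5 or gfap-Cre-negative 1, 3 or 4 (endothelial). Others there were gfap-Cre-positive 3 or 4 or gfap-Cre-negative 1, 2 or 6 (heat shock), gfap-Cre-positive 2 or gfap-Cre-negative 1, 2 or 4 (hippocampal), gfap-Cre-positive 5 or 6 or gfap-Cre-negative 4 (oligodendrocyte), and gfap-Cre-negative 3 (presynaptic). For the difference these were syn-Cre-negative 2 or gfap-Cre-positive 3 (immediate early), syn-Cre-negative 4, gfap-Cre-positive 5 or gfap-Cre-negative 6 (mitochondrial), and 14 of the 24 libraries for cerebellar genes: syn-Cre-positive 3 or 5, syn-Cre-negative 2, 4, 5 or 6, gfap-Cre-positive 1, 4, 5 or 6, and gfap-Cre-negative 1, 4, 5 or 6. The other 12 list results kept their call whichever library was left out. Depth limits the genes below 1 CPM, such as Tph1 with 4 to 118 counts per syn library and Afmid with 17 to 47.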

Other observations

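The list tests of the Cre-negative groups, the choroid plexus covariate and the choice of the genes named for them were made only after the count of differing genes was seen; the regroupings were set beforehand, those of the lists after the list results were known.

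Between the Cre-negative groups, choroid plexus genes were higher in the syn line in 16 of 16 members, all of which passed over all genes tested, with a median log2 fold change of 3.76 (Ttr 4.78, Folr1 4.22; camera adjusted p = 0.000127, adjusted p = 0.575 with an estimated correlation). The syn libraries were uneven: Ttr was 4793, 5015 and 3702 CPM in syn-Cre-negative 3, 4 and 6, and 73.0, 97.5 and 79.8 CPM in 1, 2 and 5, within the 27.8 to 162 CPM of the gfap-Cre-negative group. Genes of ependymal cells, which line the ventricles, were higher in 13 of 13, 12 of them passing over all genes, with Foxj1 at 1.38 and Tmem212 at 1.81 (2.6e-10; adjusted p = 0.408 with an estimated correlation). Myelin genes of oligodendrocytes were higher in 16 of 16, 13 passing over all genes, with Mobp at 0.57 and Mbp at 0.32 (9.0e-06; adjusted p = 0.572 with an estimated correlation). Adjusted over the list alone, 16 choroid plexus, 13 ependymal and 14 oligodendrocyte genes passed.

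Neuronal genes were lower in the syn line's Cre-negative group in 17 of 18 members, 13 passing over all genes and 16 adjusted over the list alone, with Snap25 and Syt1 at −0.22 each (1.5e-06; adjusted p = 0.408 with an estimated correlation). Genes of GABA synthesis, transport and receptors were lower in 20 of 20, 10 passing over all genes and 13 adjusted over the list alone, with Gad1 at −0.19 (0.000117; adjusted p = 0.408 with an estimated correlation). Nuclear genes of oxidative phosphorylation were lower in 31 of 31, 18 passing over all genes and 21 adjusted over the list alone (camera adjusted p = 8.9e-06, and 0.575 with an estimated correlation). Of the 44 lists, 20 passed camera between these groups, 0 passed with an estimated correlation and 22 passed fry's test of 1 direction. Ttr ran from 44.9 to 5015 CPM in the syn libraries and from 21.0 to 224 CPM in the gfap libraries. With the choroid plexus score as a covariate 5096 genes differed between the Cre-negative groups, 4614 of them among the 6161.

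In 100 regroupings of the samples, the real one included, chance could not be excluded for the count of genes in either arm. For the neuronal arm 9 gave as many as the real 1, the highest other being 121, and for the astrocytic arm 8 gave as many as the real 2, the highest other being 1020. These shares weigh only how many genes are called and not how large a change is. Prm1 and Prickle2 each showed no overlap between the 6 Cre-positive and 6 Cre-negative gfap libraries. Chance gives this in 0.216% of genes, so some such genes would arise by chance among all those tested. Both genes were picked for the smallest p in these same libraries, so their lack of overlap alone does not weigh against chance. Their edgeR adjusted p values, given with the astrocytic arm, do allow for the choice among all 19726 genes. Those values rest on the size of each change against the spread between animals, which neither the overlap nor the count of genes weighs. Regroupings that call many times the real count may reflect structure among the samples that the groups do not describe, which was not tested. For the count of 2 genes that differ between the arms, 3 regroupings gave as many (highest other 15), fewer than the limit set beforehand. These regroupings shuffle Cre labels within both lines at once. They stand for no Cre effect in either line, so they do not test a difference between the arms. Chance was excluded for the count of 6161 between the Cre-negative groups (1 regrouping, highest other 1539). The number of lists passing the preset camera test did not exclude chance: 68 regroupings reached the 10 of the neuronal arm (highest other 25), 19 the 12 of the astrocytic arm (17) and 81 the 7 of the difference (23). For the 3 lists passing with an estimated correlation in the neuronal arm, only the real grouping reached that count, and the highest other was 2. The limit for excluding chance was met, but it was set after the list results were known. Chance is therefore not firmly excluded for this count. That count is fragile, as each of the 3 lists had an adjusted p of 0.0486, the glucocorticoid and cholesterol lists passed in 0 of 12 cases and the clock list in 2 of 12 when 1 library was left out, and fry's test of 1 direction passed 0 lists.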
